A study of Arabidopsis thaliana with 24 samples.

How the data were processed

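Gene expression was measured in Arabidopsis thaliana seedlings, 7 days old, grown with 16 h of light and 8 h of dark. Wild type (Col-0), the single mutants gi-2 and elf4-209 and the gi-2 elf4-209 double mutant were harvested at ZT1 and ZT16, that is 1 h and 16 h after lights on. Each of the 8 groups had 3 samples, and each of the 24 samples was hybridised to 1 Agilent array with 1 colour (Cy3). Groups and replicate numbers were taken from the labels. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples.

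The deposited scanner files hold intensity values: per the file headers, gProcessedSignal is the spot intensity after Agilent Feature Extraction 10.7.1.1 had subtracted background and corrected trends across the slide. The same files give the raw median intensity of each spot and of its local background, per the file headers. The authors' processed values are on a log2 scale. Comparison with the scanner files showed that they equal log2 of the raw median intensity, quantile-normalized apart within the 12 arrays of each time point and with no background subtraction, with a largest difference of 5e-07. Column medians were 7.85 to 7.93. These values were used only as an alternative and only for comparisons within a time point, because the time points had been normalized apart. RNA was extracted with WelPrep reagent and treated with DNase I, and labelling refers to the Agilent manual, per the labels.

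Each array held 62976 spots, of which 61657 belonged to 43603 gene probes and 1319 were controls. Spots with an outlier mark were left out, which removed 92 probes, and duplicate spots were averaged. Signals were expressed as log2 of gProcessedSignal minus the array's 75th percentile. A probe was kept where it was well above background on all 3 arrays of at least 1 group, which left 29974 probes, 68.7% of the gene probes. Between 62.9% and 70.9% of the gene probes were well above background on each array, the 75th percentile was 12.1 to 41.7 times the local background, and only 2 gene spots were saturated over all arrays. The number of arrays limits the precision.

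The files used here identify probes by an array ID and do not pair them with genes. None of the IDs was found in the reference table of gene names, which gave 0 matches. Results are therefore given for probes, and several probes can belong to 1 gene. The 19 gene lists and the rule for named genes fixed before the data were examined need gene names and were not applied, nor was the average over the probes of a gene. For the same reason the transcripts of GI and ELF4 were not examined as a check of the genotypes. In their place, 4 probes are named that were chosen after their values were seen: the highest and the lowest log2 difference from wild type at ZT16 in each single mutant, among probes past the threshold with the same sign on every slide.

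All 24 arrays entered 1 model with a mean for each of the 8 groups (limma 3.58.1 in R 4.3.3, lmFit and eBayes). Probes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called, with no fold minimum. The 18 comparisons were wild type between times, each mutant against wild type, the mutants against each other, the departure of the double mutant from the sum of the single effects, and the change of each mutant effect between times. For the position of the double mutant between the single mutants, probes were those called between gi-2 and elf4-209 at that time, a choice that uses no double-mutant mean. Shares of the 3 double-mutant arrays were compared between times with a two-sided exact permutation test, whose smallest p is 0.1. The test does not keep arrays of the same slide together. Where a probe was not well above background on any array of a group, the fold is a bound. The brighter group's mean was then set against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

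Each replicate number corresponded to 1 slide and 1 scan day, and each of the 3 slides held all 8 groups, so the slide was also fitted as a block. Each group lay at the same position on every slide, so position and group cannot be told apart. Deviations from the group means correlated by 0.399 on average between arrays of the same number, over 84 pairs. They correlated by -0.195 between arrays of different numbers, over 168 pairs. Deviations from a group mean cancel within the group, so this negative value follows largely from the positive one and is no separate evidence of pairing. Of the 84 pairs, 77 lay above 0.1 and the lowest was -0.107. The pairing comes from the slide as the files give it, not from the labels. The blocked count is printed beside a count where it differs by more than 1.5 times.

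After the data were examined, 2 arrays labelled ZT1 were found to lie near the ZT16 arrays: gi-2 replicate 3 and elf4-209 replicate 3. They keep their labels, and each count is also given for the 22 other arrays. The time position of an array, the day-night difference on a slide not used to choose the probes, the squared distances between genotypes, with their error from the differences within slides, and the use of the spike-in ratio were likewise chosen after the data were examined. The time position is the median, over the 1652 probes called at least 2-fold apart between the wild-type times, of the array's distance from the wild-type ZT1 mean over the wild-type time difference. The spike-in ratio is the log2 signal of the 10 E1A spike-in probes minus the log2 75th percentile of the gene probes.

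The alternatives set before the data were examined were quantile normalization, median centring, normexp background correction (offset 50) with quantile normalization, the authors' processed values, no filter or a filter on all 24 arrays, a fit of only the groups compared, a trended and robust prior, array weights, the slide block, a minimum of 2-fold, and leaving out each slide and each array. The normexp alternative used the raw median signal, since the mean signal was not used here. The model was tested on simulated data for gi-2 against wild type at ZT16 over 29974 probes, 200 of them changed, with slide effects. It recovered 8.96% of the changes of 1.5-fold, 43.3% of 2-fold and 75.8% of 4-fold, with 1 false call. The slide block recovered 14.9%, 64.2% and 80.3%, with 2 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.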

Results

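The series asked whether GIGANTEA (GI), a circadian clock-associated regulator of flowering, and EARLY FLOWERING 4 (ELF4), a member of the clock's evening complex, dominate over each other at different times of the day. Transcript levels were measured with 29974 probes in wild type, gi-2, elf4-209 and gi-2 elf4-209 seedlings at ZT1, near dawn, and at ZT16, at dusk. Each of the 8 groups had 3 arrays. Between 62.9% and 70.9% of all gene probes were well above background on an array, and the lowest correlation between 2 arrays of a group was 0.946 across probes. The double mutant at ZT1 lay at the low end, with 62.9%, 63.4% and 63.1% on replicates 1, 2 and 3. Double-mutant replicate 1 at ZT16 also had 62.9%, while wild type at ZT1 had 66.7% to 70.9%. The lowest 75th percentile over local background, 12.1, was on double-mutant ZT1 replicate 3.

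In wild type, 2698 of 29974 probes differed between ZT16 and ZT1: 1434 were higher and 1264 were lower at ZT16. The median size of these differences was 1.16 on the log2 scale, and the range was -8.30 to 7.82. Of the called probes, 1652 differed at least 2-fold and 2697 had the same sign on all 3 slides. With the slide as a block, limma called 6086 probes, 2968 higher and 3118 lower; with 22 arrays it called 3889, or 7249 with the block. The count rested on all but 1 of the wild-type arrays: it was 1117 without ZT1 replicate 1, 1238 without ZT1 replicate 3, 1798 without ZT16 replicate 1, 1326 without ZT16 replicate 2 and 1313 without ZT16 replicate 3. Without the whole of slide 1, 2 or 3 it was 1108, 49 and 1467.

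Over probes chosen by their day-night difference in wild type, the single mutants held a smaller difference than wild type on slides 1 and 2. No probes were chosen from a mutant, so an equally large day-night difference in other probes would not be seen. On slide 1, for 2714 probes chosen from wild type on the other slides, the median signed difference was 1.38 in wild type (log2), of which gi-2 kept 79.7%, elf4-209 78.7% and the double mutant 72.9%. On slide 2, gi-2 kept 76.1%, elf4-209 76.5% and the double mutant 65.6% of a wild-type difference of 1.06. On slide 3 the double mutant kept 59.9% of a wild-type difference of 1.35, while the median was 0.00 in gi-2 and 0.03 in elf4-209. The array labelled gi-2 ZT1 replicate 3 lay at 0.865 between the wild-type times (0 for ZT1 and 1 for ZT16), and the array labelled elf4-209 ZT1 replicate 3 at 0.853. The other ZT1 arrays of the mutants lay between 0.0964 and 0.324, and the ZT16 arrays of the mutants between 0.820 and 0.930. Each of these 2 arrays correlated best with a ZT16 array of its own genotype, with r of 0.992 across probes. Counts below are given for the arrays as labelled and for the 22 other arrays.

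**Figure D1:**
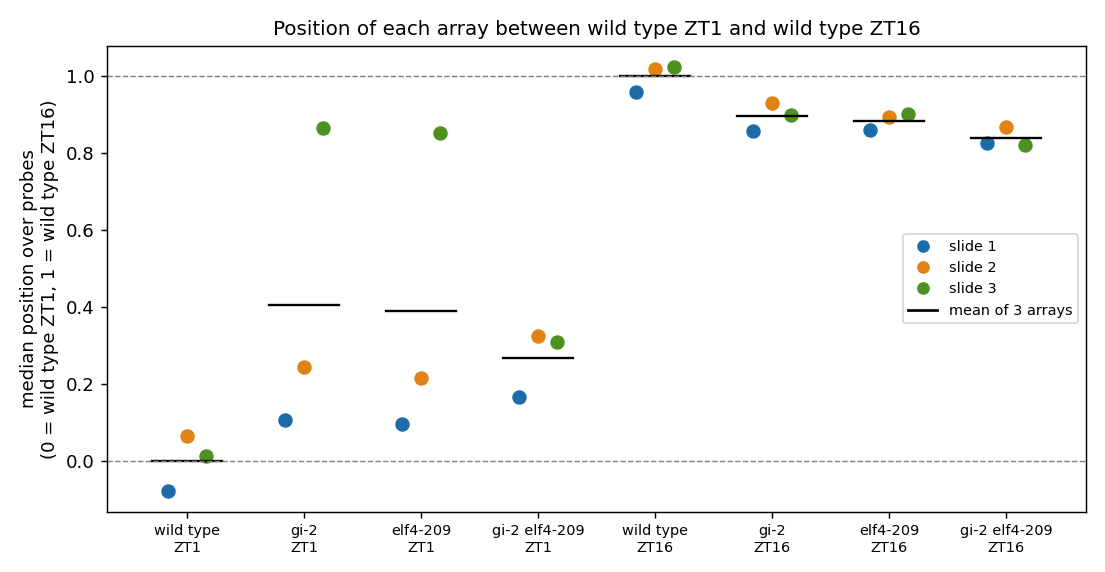
Median position of each of the 24 arrays between the wild-type means at ZT1 (0) and ZT16 (1), over 1652 probes. Points are arrays coloured by slide and bars are means of 3 arrays; the slide 3 arrays labelled gi-2 ZT1 and elf4-209 ZT1 lie at 0.865 and 0.853, beside the ZT16 arrays.

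To ask what GI does alone, gi-2 was compared with wild type at each time. At dusk, 36 probes differed: 21 were higher and 15 lower in gi-2, with a median size of 2.28 (log2). The lowest was A_84_P17055, at -1.02 ± 0.38 in wild type (log2 relative to the array's 75th percentile, SD, n = 3) and not well above background on any gi-2 array (mean -7.42 ± 0.14). It was at least 21.7-fold lower in gi-2 (limma adjusted p = 0.00534). In elf4-209 this probe was at -0.71 ± 0.22, and in the double mutant it was at least 19.3-fold lower than in wild type (adjusted p = 0.00141). The highest was A_84_P18763, at -3.39 ± 0.82 in gi-2 and not well above background on any wild-type ZT16 array (mean -7.17 ± 0.11), at least 3.48-fold higher (adjusted p = 0.0332). It was also at least 3.63-fold higher in elf4-209 (adjusted p = 0.0179) and at least 10.4-fold higher in the double mutant (adjusted p = 0.000198). The gi-2 call of A_84_P18763 was lost in 11 of 21 other settings and that of A_84_P17055 in 2 of 21. These folds depend on the background subtraction. The log2 difference of A_84_P17055 was -6.40, but -2.82 with normexp and -2.78 with the authors' values, and that of A_84_P18763 was 3.78, but 1.31 with the authors' values and close to this with normexp. These smaller values lie below the bounds given above.

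At dawn, 26 probes differed between gi-2 and wild type: 14 were higher and 12 lower. Without the 2 arrays the count was 24, and 17 of the 26 kept their call. The slide block gave 76 probes at ZT16 and 125 at ZT1, of which 94 were higher and 31 lower; with 22 arrays, ZT16 gave 71, or 189 with the block, and ZT1 gave 63 with the block. Single arrays moved these counts. At ZT16 the count was 16 without wild-type replicate 1, 19 without wild-type replicate 2, and 19, 16 and 18 without gi-2 replicate 1, 2 or 3. At ZT1 it was 16 without wild-type replicate 2, 55 without gi-2 replicate 1 and 17 without gi-2 replicate 3.

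The matching comparison for ELF4 gave more probes in most settings. The order turned at ZT1 with array weights (63 for gi-2, 60 for elf4-209) and at ZT16 with the block and the spike-in ratio as a covariate (79 and 58). At dusk, 61 probes differed between elf4-209 and wild type: 43 were higher and 18 lower, with a median size of 2.33 (log2). The highest was A_84_P137629, which rose from -4.26 ± 0.33 in wild type to -0.05 ± 0.18 in elf4-209, 18.5-fold (adjusted p = 0.0150). The double mutant was 14.4-fold higher than wild type for it (adjusted p = 0.0102) and gi-2 was at -2.91 ± 0.53, which did not pass (adjusted p = 1.00). The lowest was A_84_P15757, at 1.65 ± 0.10 in wild type and -3.09 ± 1.07 in elf4-209, 26.8-fold lower (adjusted p = 8.91e-08). It was at 1.91 ± 0.09 in gi-2 and 2.03 ± 0.08 in the double mutant, neither of which passed against wild type. The same probe was at 2.02 ± 0.26 in wild type and -3.51 ± 0.14 in elf4-209 at ZT1. Because the double mutant kept the wild-type level, a difference of the elf4-209 single-mutant line other than ELF4 is not excluded for this probe; it was not tested. The call of A_84_P137629 was lost in 10 of 22 other settings, and that of A_84_P15757 in 0 of 22. The log2 difference of A_84_P137629 was 4.21, but 3.09 with normexp and 3.07 with the authors' values, and that of A_84_P15757 -4.75, but -4.07 and -4.04.

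At dawn, 109 probes differed between elf4-209 and wild type: 60 were higher and 49 lower, with a median size of 1.57 (log2). Without the 2 arrays the count was 182, and 85 of the 109 kept their call. The slide block gave 108 probes at ZT16 and 476 at ZT1; with 22 arrays, ZT16 gave 96, or 193 with the block, and ZT1 gave 607 with the block. At ZT16 the count was 39 without wild-type replicate 1, and 35, 40 and 39 without elf4-209 replicate 1, 2 or 3. At ZT1 it was 41, 38 and 55 without wild-type replicate 1, 2 or 3, and 48 without elf4-209 replicate 1.

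The single mutants shared some called probes. Across all probes at ZT16, the covariance of their effects lay little above what the shared wild-type arrays alone would give. At ZT16, 13 probes were higher in both single mutants and 1 was lower in both, with 1 in opposite directions; independent lists would share 0.0301 and 0.00901, which leaves out the shared wild-type arrays. At ZT1, 13 were higher in both, 4 lower in both and 2 opposite, against 0.0280 and 0.0196 for independent lists. The effects correlated by 0.221 across probes at ZT16, and unchanged groups simulated against the same wild-type arrays gave 0.501. The covariance was 0.0255 at ZT16, against 0.0230 simulated. The simulated groups carry no effects, and effects particular to each mutant lower a correlation. The lower correlation at ZT16 therefore does not show that the effects were less alike than simulated. At ZT1 the correlation was 0.683 against 0.50 simulated and the covariance 0.0969 against 0.0406; without the 2 arrays these were 0.561 against 0.399 and 0.0635 against 0.0329. How much of the overlap of calls comes from the shared wild-type arrays was not tested, as they are too few to split.

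Against each other, gi-2 and elf4-209 differed in 24 probes at ZT1 and 37 at ZT16. The slide block gave 46 and 131, the 22 arrays 33 and 85, and both together 105 and 585. The ZT1 count was 41 without elf4-209 replicate 3.

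The double mutant differed from wild type in more probes than either single mutant, and in more at dawn than at dusk; the order of the times depended on the fit. At ZT1, 8368 probes differed: 3965 were higher and 4403 lower, with a median size of 0.99 (log2), and 4137 differed at least 2-fold (1317 higher, 2820 lower). On all 3 slides 8340 of them had the same sign. At ZT16, 354 probes differed: 254 were higher and 100 lower, with a median size of 1.42. Of the probes called at both times, 93 were higher at both, 57 lower at both and 19 opposite. The 2 sets of effects share no array and correlated by 0.546 across probes, which are not independent replicates. The E1A spike-in signal over gene signal was also higher in the double mutant at ZT1 than in wild type on the same slide, by 1.42, 0.83 and 1.36 on slides 1, 2 and 3 (mean 1.21 ± 0.32 SD, log2, n = 3). At ZT16 the mean difference was 0.26 ± 0.39. With the slide block and the spike-in ratio as a covariate, 1654 probes differed at ZT1 and 2356 at ZT16, so the order of the times turned.

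The split of the ZT1 calls between higher and lower depended on scaling and on the fold minimum. Median centring gave 6483 higher and 3097 lower and moved the median of all probes by 0.21 (log2). The slide block gave 13879 probes at ZT1 and 2713 at ZT16, where the majority turned to lower (1194 higher, 1519 lower), and the 22 arrays 8871 and 517, or 14817 and 3639 with the block. At ZT1 the count was 3058 without double-mutant replicate 1, 4028 without wild-type replicate 2 and 4037 without wild-type replicate 3. At ZT16 it was 212, 196 and 219 without wild-type replicate 1, 2 or 3, and 172 without double-mutant replicate 1.

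**Figure D2:**
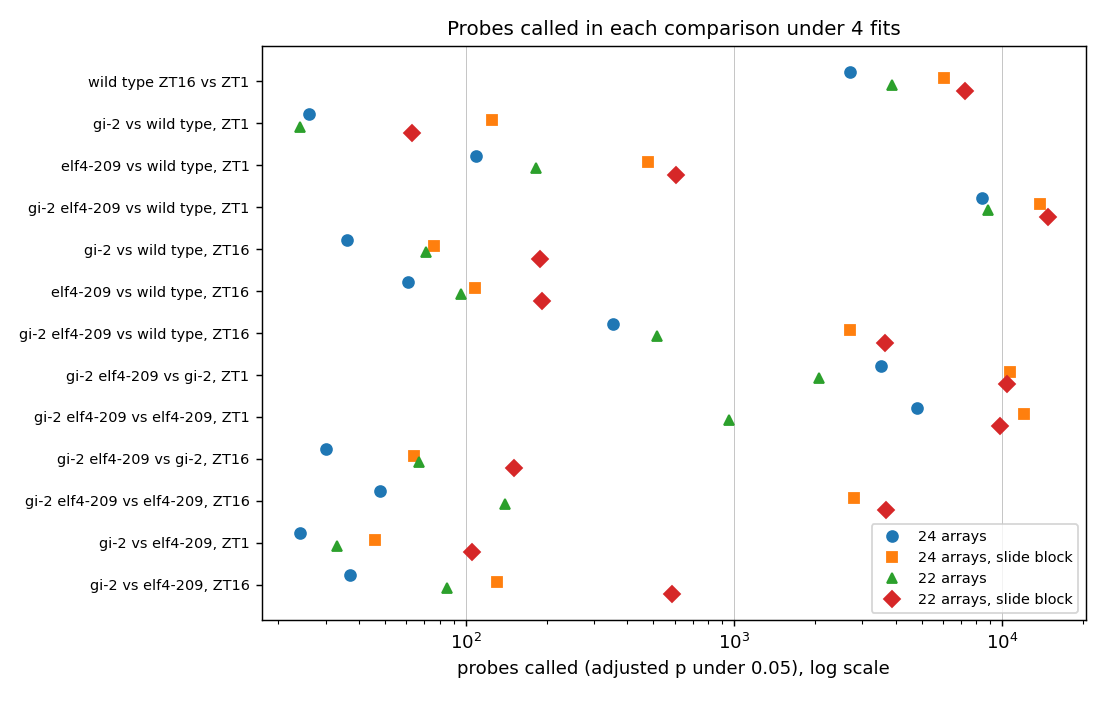
Probes called at an adjusted p under 0.05 (log axis) in 13 comparisons of 2 groups, with all 24 arrays or the 22 left without the 2 ZT1 arrays near ZT16, each without and with the slide as a block. The double mutant at ZT1 gave 8368 probes against wild type and gi-2 at ZT16 gave 36, with all 24 arrays and no block.

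**Figure D3:**
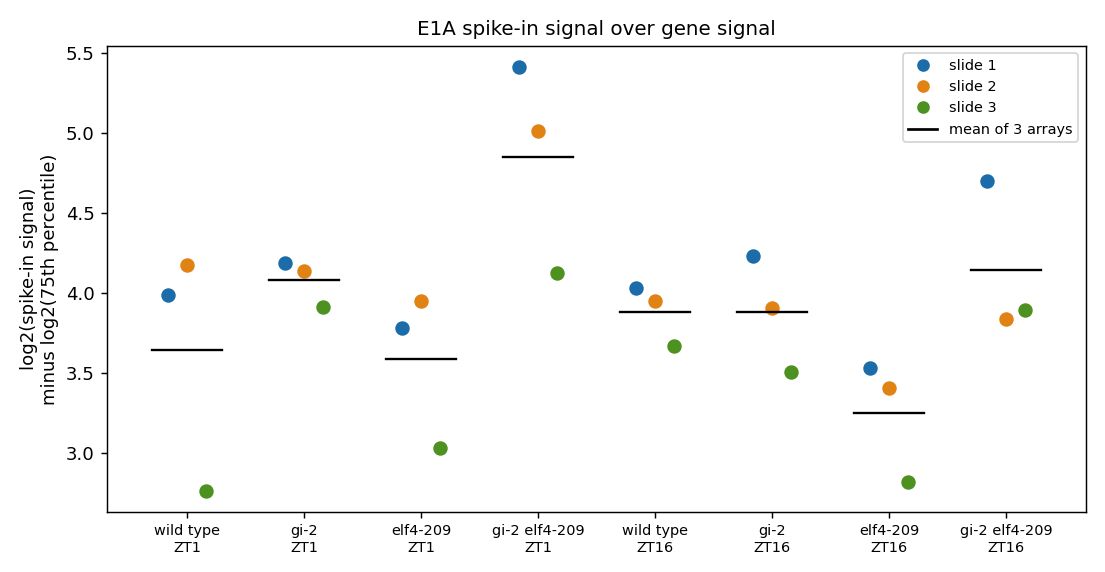
Log2 signal of the E1A spike-in probes minus the log2 75th percentile of the gene probes, for each of the 24 arrays. Points are arrays coloured by slide and bars are means of 3 arrays; the double mutant at ZT1 averaged 4.85 and wild type at ZT1 3.64.

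To ask which single mutant the double mutant resembled, it was compared with each. At dusk it differed from gi-2 in 30 probes (23 higher, 7 lower) and from elf4-209 in 48 (24 higher, 24 lower). With the slide as a block these became 64 against gi-2 and 2811 against elf4-209 (932 higher, 1879 lower). With the block and the spike-in ratio as a covariate they were 56 and 34, so the order turned. With 22 arrays they were 67 and 140, or 151 and 3700 with the block. The mean squared log2 difference over all probes, less its error within slides, was 0.06 against gi-2, 0.24 against elf4-209 and 0.22 against wild type. Within each slide the double mutant lay nearer gi-2: its squared difference from gi-2 was 0.336, 0.805 and 0.482 of that from elf4-209 on slides 1, 2 and 3. The mean over slides of the squared difference from gi-2 minus that from elf4-209 was -0.196, with an SD between slides of 0.189. It was -0.087 with normexp and -0.086 with the authors' values, and it stayed negative in the other scalings and without each slide. With 3 slides an exact sign-flip test cannot go below a two-sided p of 0.25. The spike-in ratio of elf4-209 at ZT16 was lower than that of wild type by a mean of -0.63 ± 0.19 (log2), while gi-2 differed by 0.00 ± 0.19. Without gi-2 replicate 1 or 2, or double-mutant replicate 1 or 3, the count against gi-2 was 13, 16, 12 and 17. Without elf4-209 replicate 1, 2 or 3, the count against elf4-209 was 27, 27 and 24, and without double-mutant replicate 1 or 3 it was 26 and 76. The higher and lower calls against elf4-209 were 25 and 16 with median centring, which moved the median of all probes by 0.19, 28 and 17 with normexp, and 26 and 17 with the authors' values.

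At dawn the double mutant differed from both: 3518 probes from gi-2 (1652 higher, 1866 lower) and 4827 from elf4-209 (2288 higher, 2539 lower). With the slide as a block these were 10661 and 12058 (6142 higher, 5916 lower against elf4-209), and with the spike-in ratio as a covariate as well 2527 and 60. With 22 arrays they were 2065 (1123 higher, 942 lower) and 957 (572 higher, 385 lower), or 10401 and 9823 with the block. The fit of only the groups compared called far fewer, 29 and 15, as did the fit without replicate 2, with 10 and 79. The mean squared difference less its error within slides was 0.37 against gi-2 and 0.40 against elf4-209. With 22 arrays and the error of the unblocked fit it was 0.35 and 0.29, so the order turned. With a minimum of 2-fold the majority was lower, with 559 higher and 1171 lower against gi-2 and 542 and 1726 against elf4-209. Median centring gave 3231 higher and 1290 lower against gi-2 and 4518 higher and 1932 lower against elf4-209, moving the median of all probes by 0.18 and 0.24. Against gi-2, normexp gave 1653 higher and 1164 lower, and the authors' values 1556 and 1147. The count against gi-2 was 986 without gi-2 replicate 2, 1551 without gi-2 replicate 3, 501 without double-mutant replicate 1 and 7399 without double-mutant replicate 2. The count against elf4-209 was 7601, 500 and 380 without elf4-209 replicate 1, 2 or 3, and 287 and 8744 without double-mutant replicate 1 or 2.

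Over the probes that separate the single mutants, the double mutant lay nearer gi-2 for 25 of 37 probes (67.6%) at ZT16 and for 13 of 24 (54.2%) at ZT1. Shares of the 3 double-mutant arrays were 67.6%, 62.2% and 62.2% at ZT16 and 45.8%, 58.3% and 62.5% at ZT1 (exact permutation p = 0.3, two-sided). The ZT1 share depended on the 2 arrays, whose exclusion was chosen after the data were examined. With the 22 other arrays it was 42.4% of 33 probes, against 60% of 85 at ZT16. With 22 arrays and the slide block it was 24.8% of 105 probes at ZT1 and 80.9% of 585 at ZT16. The median position of the double mutant (0 for elf4-209 and 1 for gi-2) was then 0.00 at ZT1 and 0.91 at ZT16. In that fit the shares of single arrays were 24.8% to 26.7% at ZT1 and 75.9% to 79.1% at ZT16 (exact permutation p = 0.1, two-sided, the smallest 3 against 3 arrays can give). This test ignores that the arrays of both times share slides, and it compares different probes at each time. All 3 shares of a time use the same single-mutant means, and slide effects were taken out first. Their small spread therefore leaves out the error of those means. With 24 arrays and the block the shares were 50% of 46 and 74.8% of 131. Single ZT1 arrays moved the share of the 24 arrays both ways. It was 31.7% without elf4-209 replicate 3, but 75% and 73.7% without elf4-209 replicate 1 or 2, and 68.4% and 73.7% without gi-2 replicate 1 or 2, all 4 above the 67.6% at ZT16.

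The direction between the times was not the same in every setting. The ZT1 share was the higher one with array weights (83.3% against 71.0%), in the fit of only the groups compared (78.6% against 66.7%) and without replicate 2 (85.7% against 83.3%). The ZT1 share also rested on 8 probes that were lower in elf4-209 at both times and differed in the double mutant toward the wild-type level. All 8 counted as nearer gi-2 at both times. Without them the tallies were 5 of 16 probes at ZT1 and 17 of 29 at ZT16, or 18 of 97 and 465 of 577 with 22 arrays and the block. These probes were picked after the data were examined and partly by their level in the double mutant, so their removal lowers both shares by construction. Whether they mark a difference of the single-mutant line other than ELF4 was not tested.

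**Figure D4:**
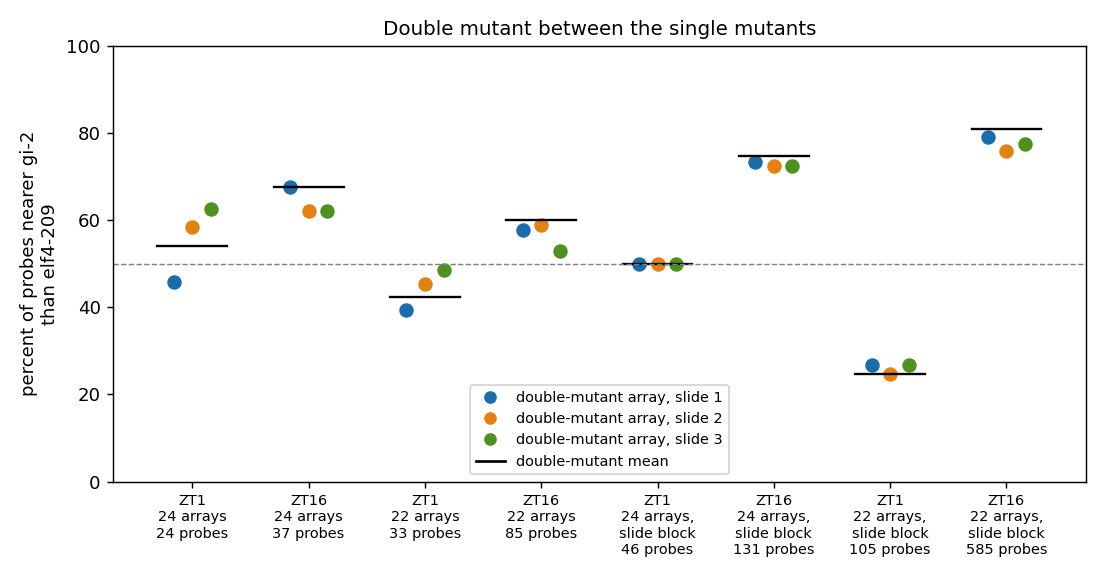
Percent of the probes called between gi-2 and elf4-209 for which the double mutant lay nearer gi-2, at ZT1 and ZT16 under 4 fits. Points are the 3 double-mutant arrays, with slide effects taken out in the blocked fits, and bars the double-mutant mean; with 22 arrays and the block the bars are at 24.8% (ZT1) and 80.9% (ZT16).

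The departure of the double mutant from the sum of the single effects was tested at each time. It passed for 14 probes at ZT1 (9 higher, 5 lower than the sum) and 10 at ZT16 (9 higher, 1 lower). Among them was A_84_P15757, 6.08 above the sum at ZT1 and 4.87 at ZT16 (log2, limma adjusted p = 1.23e-06 and 2.52e-05). It is 1 of 8 probes lower in elf4-209 at both times that lay toward the wild-type level in the double mutant. Over these 8 the elf4-209 effect was -5.53 to -2.42 at ZT1 and -4.75 to -2.17 at ZT16 (log2). A low level in elf4-209 alone is itself a departure above the sum, so all 8 lay above it at both times. The median size of the called departures was 3.76 at ZT1 and 4.27 at ZT16. How many of the 9 higher calls at each time were among the 8 was not counted. These calls may largely restate the low level in that line. Whether such calls mark a difference of the elf4-209 line other than ELF4 was not tested. Without the 2 arrays the counts were 12 and 11. The slide block gave 842 at ZT1, where the majority turned (351 higher, 491 lower), and 12 at ZT16, and 36 and 15 with 22 arrays. Without a filter on dim probes 4344 passed at ZT1, 4147 of them higher. With the block and the spike-in ratio as a covariate 22 passed at ZT1. Median centring gave 9 higher and 3 lower at ZT1, moving the median of all probes by 0.18, normexp 11 and 2, and the authors' values 10 and 2. The ZT1 count was 9 without wild-type replicate 3, 73 without elf4-209 replicate 1, 9 without elf4-209 replicate 3 and 28 without double-mutant replicate 2.

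Whether a mutant effect changed between dawn and dusk was tested directly. The gi-2 effect was higher at ZT16 than at ZT1 for 22 probes and lower for 0, with a median size of 2.53 (log2). By limma at an unadjusted p under 0.05, 376 probes were higher and 311 lower. Without any 1 of the 3 slides, 0 probes were called. The elf4-209 effect was higher for 26 probes and lower for 3, but at an unadjusted p under 0.05 for 500 and 615; without slide 1 or 2, 0 were called, and without slide 3, 14. The double-mutant effect was higher for 347 and lower for 281, and at an unadjusted p under 0.05 for 2187 and 2402. With the slide block the counts were 37, 76 and 2430; with 22 arrays they were 30, 84 and 1186, or 68, 202 and 3721 with the block. In the last fit the higher and lower counts were 51 and 17 for gi-2, 103 and 99 for elf4-209 and 1826 and 1895 for the double mutant, so the one-sided split did not hold for elf4-209. For gi-2 the count was 4 and 3 without wild-type ZT1 replicate 1 or 3, 3 and 7 without wild-type ZT16 replicate 1 or 2, 13 and 9 without gi-2 ZT1 replicate 2 or 3, and 13, 3 and 3 without gi-2 ZT16 replicate 1, 2 or 3. For elf4-209 it was 11 without wild-type ZT1 replicate 1, 12 without wild-type ZT16 replicate 1, and 14 and 10 without elf4-209 ZT16 replicate 1 or 3. For the double mutant it was 390 and 361 without wild-type ZT1 replicate 1 or 3, 392 without wild-type ZT16 replicate 2, and 408 and 338 without double-mutant ZT16 replicate 2 or 3.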

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

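The tests of the 2 ZT1 arrays near ZT16 were chosen after their positions were seen, and the splits within slides, the spike-in covariate and the test of the order of counts after the counts were seen. The other tests of the double-mutant count and of the splits were set before their values were seen.

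The arrays labelled gi-2 ZT1 replicate 3 and elf4-209 ZT1 replicate 3 lay near the ZT16 arrays. A swap with another array of the series would leave a ZT16 array near ZT1, and the lowest ZT16 array lay at 0.820 of the wild-type day-night difference. An effect of the third slide would move its other ZT1 arrays too, and the higher of those lay at 0.309. A later phase in the single mutants would show in the other replicates, whose highest value was 0.244. RNA of a ZT16 harvest under a ZT1 label stays open: the larger shortfall of the 2 arrays below their genotype's ZT16 mean was 0.0312, but for elf4-209 this is above the largest deviation among its 3 ZT16 arrays, 0.0241, and no harvest record was used here.

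The double mutant differed from wild type in 8368 probes at ZT1, and its gene signal was low against the E1A spike-ins, which the scaling does not use: the ratio was 1.21 above that of wild type (log2). Without double-mutant replicate 1 the count was 0.365 of that with it, so how much of its size rests on this array stays open, but the array does not explain the order of the counts: 3058 probes without it and 5418 without its whole slide are at least 8.64 times the highest of the other 5 mutant counts (354 and 160). If weak or degraded gene RNA were the cause, the effect should follow the spike-in slope of the other groups; across probes the correlation was 0.196, from 0.0406 to 0.326 as 1 group was left out and 0.0303 without the 2 displaced arrays; only some of these lie below the bound set beforehand, so this stays open too. A larger form of the ZT16 response, the biological alternative, gave a correlation of 0.546 with the ZT16 effect, but 74.3% of the ZT16 calls had the same sign at ZT1, below the 90% set beforehand. With the slide block, the spike-in ratio as a covariate lowered the count from 13879 to 1654 at ZT1, below the 2356 at ZT16, but the ratio itself differs between these groups, so the RNA and the response at ZT16 could not be told apart as explanations.

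The difference of an effect between groups was tested for 5 comparisons, each with 100 splits of the arrays, the real one included. Splits within slides exchange arrays only on the same slide and so keep the pairing. The gi-2 effect changed between times for 22 probes; 2 of the 100 splits gave as many and the highest other gave 61. The elf4-209 effect changed for 29 probes; 1 split, the real one, gave as many and the highest other gave 20. Within slides there are 32 splits, and for gi-2 and for elf4-209 2 of them gave as many, a share of 0.0625, so chance is not excluded for either. In both cases the other one kept the groups whole and tested the sum of the effects at both times, with 61 and 97 probes. The highest split that mixed the groups gave 2 and 16. The double-mutant effect changed for 628 probes, but 8 splits, and 6 of the 32 within slides, gave as many and the highest other gave 8607, so chance is not excluded. Within slides the split with 8607 kept the groups whole and tested the sum of the effects, and the highest that mixed the groups gave 5059. Splits that leave most of the large ZT1 effect in place call many probes whether or not the effect changes. These splits therefore cannot decide the question. Departure from additivity at ZT1 gave 14 probes, with 13 splits as large and 4148 in the highest other, and 7 of 100 within slides, so chance is not excluded. At ZT16 it gave 10 probes, with 3 splits as large and 133 in the highest other, and within slides 1 of 100, the real one, with 8 in the highest other; with the block 2 of 100 gave as many as the real 12, with 44 in the highest other. The splits for additivity exchange arrays of genotypes that differ from each other, so they test more than additivity and do not exclude chance. The ZT16 calls include A_84_P15757, 1 of 8 probes lower in elf4-209 at both times and toward the wild-type level in the double mutant. All 8 lay above the sum, and how many of them were called was not counted. Without slide 2 the ZT16 count fell to 2. Other splits that called several times the real count show a structure of the samples that is not the tested difference.

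For the 13 comparisons of 2 groups, 3 arrays against 3 make 10 splits, and 4 within slides, too few for a share under 0.05. In 12 of them only 1 split, the real one, gave as many probes. The highest other split gave 5 for the double mutant against gi-2 at ZT1 (real 3518), 4 for the same at ZT16 (real 30) and 0 for wild type between times (real 2698), gi-2, elf4-209 and the double mutant against wild type at ZT1 (26, 109 and 8368) and at ZT16 (36, 61 and 354), the double mutant against elf4-209 at ZT1 and ZT16 (4827 and 48) and gi-2 against elf4-209 at ZT16 (37). For gi-2 against elf4-209 at ZT1, 3 of the 10 splits gave as many as the real 24. The highest gave 417 and put the 2 displaced arrays with gi-2 replicate 2 on one side.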

How the results depend on the processing

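The fits without the 2 ZT1 arrays near ZT16 and the fit with the spike-in ratio were added after the results were seen; all other settings were set before. Quantile normalization and median centring kept all 20 results within the bounds of 1.5 times for a count and 1 SD between arrays for a share. No comparison against wild type lost all its calls under a setting that kept every array. In the simulation of gi-2 at ZT16, with 200 probes changed, 75.8% of 4-fold changes and 8.96% of 1.5-fold changes were recovered. Small changes are thus mostly not called where few probes change. This does not carry over to the double mutant at ZT1, where 8368 probes were called and 4137 of them differed at least 2-fold. The lowest signal over background of an array was 12.1. Where a result moved and no reason is given, the cause was not tested. Tests of gene lists, the mean over a gene's probes and the authors' values for the wild-type time comparison and the 3 changes of effect between times were not run.

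Results are listed in a fixed order: wild type between times; at ZT1 and then at ZT16, gi-2, elf4-209 and the double mutant (D) against wild type, D against gi-2, D against elf4-209, gi-2 against elf4-209 and departure from additivity; the change of the gi-2, elf4-209 and D effects between times; and the share nearer gi-2. With the slide as a replicate block, wild type gave 6086, ZT1 gave 125, 476, 13879, 10661, 12058, 46 and 842, and ZT16 gave 76, 108, 2713, 64, 2811 and 131; the changes between times gave 37, 76 and 2430 and the ZT16 share was 74.8%. The block changed no other result past the bounds. Array weights gave 7241 for wild type, then at ZT1 63, 60, 6103 (D against gi-2) and 352 (D against elf4-209), and at ZT16 204, 264, 1700, 89, 630, 587 and 16. The changes between times were then 48, 64 and 2612 and the shares 83.3% and 71.0%.

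Without the 2 arrays, elf4-209 at ZT1 gave 182, D against gi-2 2065 and D against elf4-209 957. ZT16 gave 71 (gi-2), 96 (elf4-209), 67 and 140 (D against each) and 85 (gi-2 against elf4-209), the elf4-209 and D effects changed for 84 and 1186, and the shares were 42.4% and 60%. Without the 2 arrays and with the replicate block, wild type gave 7249, ZT1 gave 63, 607, 14817, 10401, 9823, 105 and 36, and ZT16 gave 189, 193, 3639, 151, 3700 and 585. The changes between times were then 68, 202 and 3721 and the shares 24.8% and 80.9%. With the replicate block and the spike-in ratio as a covariate, wild type gave 5164, elf4-209 at ZT1 576, D at ZT1 1654, D against elf4-209 at ZT1 60, departure from additivity at ZT1 22, gi-2 at ZT16 79, D at ZT16 2356 and D against gi-2 at ZT16 56, beside 34 for D against elf4-209, with a ZT16 share of 80.5%.

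No filter gave 12798 for D at ZT1, 8711 and 13763 for D against gi-2 and elf4-209, 4344 for departure from additivity and shares of 63.3% and 63.4%. Probes above background on all 24 arrays, which are fewer, gave 14 for gi-2 at ZT1, 14 for gi-2 against elf4-209 and 7 for departure from additivity, and at ZT16 22 for D against elf4-209, 17 for gi-2 against elf4-209 and a share of 82.4%. A minimum of 2-fold, which keeps fewer probes by construction, gave 1652 for wild type and at ZT1 4137, 1730 and 2268 for D against wild type, gi-2 and elf4-209. Only the groups compared, with fewer arrays for the spread, gave at ZT1 3 (gi-2), 21 (elf4-209), 1477 (D), 29 and 15 (D against each), 14 (gi-2 against elf4-209) and a share of 78.6%. The same setting gave 185 for D at ZT16, 24 for gi-2 against elf4-209 and 4 for the change of the gi-2 effect. The ZT16 share was 63.2% with normexp, 62.5% with the authors' values and 73.5% with a trended and robust prior.

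Leaving out each slide (without replicate 1, 2 or 3) or each array, the ranges were 49 to 2355 for wild type. At ZT1 they were 2 to 55, 20 to 80, 2171 to 10725, 10 to 7399, 79 to 8744, 14 to 41 and 6 to 73 in the order above. At ZT16 they were 3 to 26, 26 to 48, 84 to 322, 8 to 29, 10 to 130, 18 to 36 and 2 to 12. The changes between times ranged over 0 to 22, 0 to 34 and 20 to 744, and the shares over 31.7% to 85.7% at ZT1 and 57.1% to 83.3% at ZT16. The difference of squared distances, D to gi-2 minus D to elf4-209 at ZT1, here the mean over slides of each slide's squared differences with no error subtracted, was -0.0238 and ranged from -0.114 to 0.0515; it reversed without replicate 3, to 0.0515. Without the 2 arrays, both on slide 3, the distances also stood in the reverse order, 0.349 to gi-2 and 0.293 to elf4-209, and the cause was not tested. With the error of the unblocked fit, which ignores the slides, the ZT16 distances were -0.017 to gi-2, 0.171 to elf4-209 and 0.177 to wild type.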

Other observations

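The sets below were chosen after the data were seen. Single-mutant calls fell largely on probes that differ between dawn and dusk in wild type. These make up 9.0% of all probes, but 65.4% of the calls in gi-2 and 72.5% in elf4-209 at ZT1, and 61.1% and 67.2% at ZT16. In the double mutant they made up 46.3% of the calls at ZT16 and 895 of the 8368 calls at ZT1, a share close to that among all probes. Of the probes higher than wild type at ZT16, 17 of 21 in gi-2, 37 of 43 in elf4-209 and 132 of 254 in the double mutant were among those with their wild-type level higher at ZT1. At ZT1 the direction was the opposite: 12 of the 14 probes higher in gi-2 and 46 of the 60 higher in elf4-209 were among those with their wild-type level higher at ZT16. The wild-type arrays enter both comparisons, so chance values in them push these shares up, and the ZT1 counts include the 2 displaced arrays. In the double mutant at ZT1, 547 of the 3965 higher probes were higher at ZT16 in wild type and 42 were higher at ZT1. Of the 4403 lower probes, 269 were higher at ZT1 in wild type and 37 were higher at ZT16. Most of these 895 calls thus lay in the direction of the wild-type ZT16 level, though their share of all calls was close to that among all probes. The shared wild-type ZT1 arrays push the same way.

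Some probes differed from wild type at both times. In gi-2, 2 probes were higher and 7 lower at both times, and in elf4-209 6 were higher and 13 lower; independent lists would share at most 0.0861. Of the 13 probes lower in elf4-209 at both times, 4 were also lower in the double mutant at both times. Another 8 differed between the double mutant and elf4-209 at both times, toward the wild-type level. The median effect over the 13 was -4.13 in elf4-209 and -0.03 in the double mutant (log2). Of the 7 probes lower in gi-2 at both times, 4 were lower in the double mutant at both times and 1 lay toward the wild-type level at both. Of the 6 probes higher in elf4-209, 4 were higher in the double mutant at both times and 2 lay below elf4-209 at both. Of the 2 higher in gi-2, 1 was higher in the double mutant at both times. The other, A_84_P22244, lay below wild type in the double mutant (-3.41 at ZT1 and -3.74 at ZT16, log2) and in elf4-209 (-4.61 and -4.13). Probe positions in the genome were not used here, so whether the 8 probes lie together and mark a difference of the elf4-209 line was not tested.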
